A study of Mus musculus with 12 samples.

How the data were processed

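Total RNA of 12 samples of the mouse ES cell line D3 was hybridised to Affymetrix arrays: undifferentiated cells, day 4 EBs, and EBs treated for 12 h with DMSO or ATRA, 3 samples each. Per the labels' protocols, RNA was extracted with RNeasy kits and biotinylated single-stranded cDNA was made with the Ambion WT Expression kit. The authors deposited 1 table of log2 values with 35556 probe sets per array. The log2 scale is inferred from the values, which run from 2.30 to 14.7, since the labels name neither the log base nor the background correction, normalization or summarization, which are not given in the sources used here. The array medians lie between 7.76 and 7.86 and the interquartile ranges between 3.50 and 3.65, so the arrays had been put on nearly one distribution, and values were not centred per probe set. Such a normalization hides any change of total RNA per cell, and high values can be compressed. ES replicate 2 and EB replicate 2 had the narrowest spreads. No pair of arrays was a copy: at most 0.0562% of probe sets had identical values in 2 arrays, and replicates correlated at 0.992 to 0.997.

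Probe sets were named through the platform annotation. Of the 35556, 21789 had exactly 1 symbol, 1621 had several and 12146 were unlisted there. The gene identifiers of 21698 single-symbol probe sets were found in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. A gene was represented by its single-symbol probe set with the highest mean over the 12 arrays, which gave 19938 genes. Probe sets with no or several symbols were left out, and no filter on low values was applied. Some list genes, T among them, were not analysed here. Other probe sets of the named genes were compared, and none was called in the opposite direction.

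The fit used limma 3.58.1 in R 4.3.3: lmFit with a mean per group over all 12 arrays, contrasts and eBayes with default settings (8 residual and 3.93 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Gene lists, 25 in all, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and with an estimated correlation and fry as alternatives. The comparisons, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined. The rule names, per comparison, the 8 largest rises and 8 largest falls among called genes with non-overlapping groups, leaving out predicted genes, microRNAs and olfactory and vomeronasal receptors; up to 4 called members of each list by smallest adjusted p, or 2 with the largest change where none was called; and a set of check genes. Not every gene that the rule allows is printed. The p-values measure the spread between samples that the labels call biological replicates.

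The same code was tested on simulated data with the gene means and spreads of these arrays and 200 genes changed. For ATRA against DMSO, over 19938 genes, it made 171 calls, 11 of them false, and recovered 26% of genes changed by 0.25, 94% of those changed by 0.5 and 100% of those changed by 1 or 2 on the log2 scale. The simulated noise was independent between genes, and far fewer genes changed than the 2655 called in the data. These rates therefore check the code and need not hold for the real arrays. Alternatives were quantile normalization, median centring, filters on mean value, the mean of a gene's probe sets, all probe sets, an intensity trend with a robust prior, array weights, only the 2 groups compared, the replicate number as a block, each array left out, an adjusted p of 0.01, and a 1.5-fold limit. Leaving out ES replicate 2 and EB replicate 2 together was added after the array summaries were seen. Overlaps of comparisons that share arrays were set beside 20 simulated sets without any change. Lists for interferon-stimulated genes, 2-cell-stage genes, the Mir17 cluster and the region from Dlk1 to Dio3 were drawn up after the values were seen. All tests of explanations were chosen after the results were seen, and 5 replaced a first version whose result had been seen. Those first versions were a Poisson test of independent gene lists (dropped because genes are not independent), a split test on correlations, a correlation after removal of technical terms, a percentile of the Dlk1 region among random sets, and a count of fibroblast genes that restated its pattern.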

Results

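Gene expression was measured on Affymetrix arrays in 12 samples of a clone of the mouse embryonic stem (ES) cell line D3. The samples fall into 4 groups of 3, which the labels call biological replicates: undifferentiated ES cells at day 0, embryoid bodies (EBs, aggregates that form when ES cells are cultured without LIF) at day 4, EBs treated for 12 h with the solvent DMSO, and EBs treated for 12 h with all-trans retinoic acid (ATRA, the active form of vitamin A) at a labelled concentration of 5 micromolar. The labels do not settle whether the 12 h lay within the 4 days or followed them. Each array gave log2 values of 35556 probe sets, with array medians between 7.76 and 7.86, and 19938 genes were tested. With 3 arrays per group, the number of arrays limits the precision. Changes below are log2 differences ± SE from the fit to all 12 arrays (n = 3 per group), and levels are log2 means ± SD (n = 3). Rankings of genes by size of change are among the genes that the naming rule allows.

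As a check of the labels, known targets of ATRA, pluripotency genes and a germ-layer gene were read in every group. Cyp26a1, which encodes the main retinoic acid-degrading enzyme, stood at 7.84 ± 0.12 in ES cells, 9.06 ± 0.11 in day 4 EBs, 9.82 ± 0.14 with DMSO and 11.58 ± 0.12 with ATRA. Rarb, a retinoic acid receptor gene, was at 8.01 ± 0.07, 7.02 ± 0.07, 6.98 ± 0.19 and 8.65 ± 0.12 in the same order. The pluripotency genes Pou5f1 and Nanog were near the upper end of the array's range in every group: Pou5f1 at 13.33 ± 0.02 in ES cells and 13.39 ± 0.03 with ATRA, Nanog at 13.47 ± 0.07 and 13.29 ± 0.01. A change at such levels can be compressed on an array. The endoderm gene Sox17 was at 8.34 ± 0.22 in ES cells, 8.99 ± 0.12 in day 4 EBs, 9.16 ± 0.06 with DMSO and 8.88 ± 0.01 with ATRA. T was not analysed here.

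**Figure D1:**
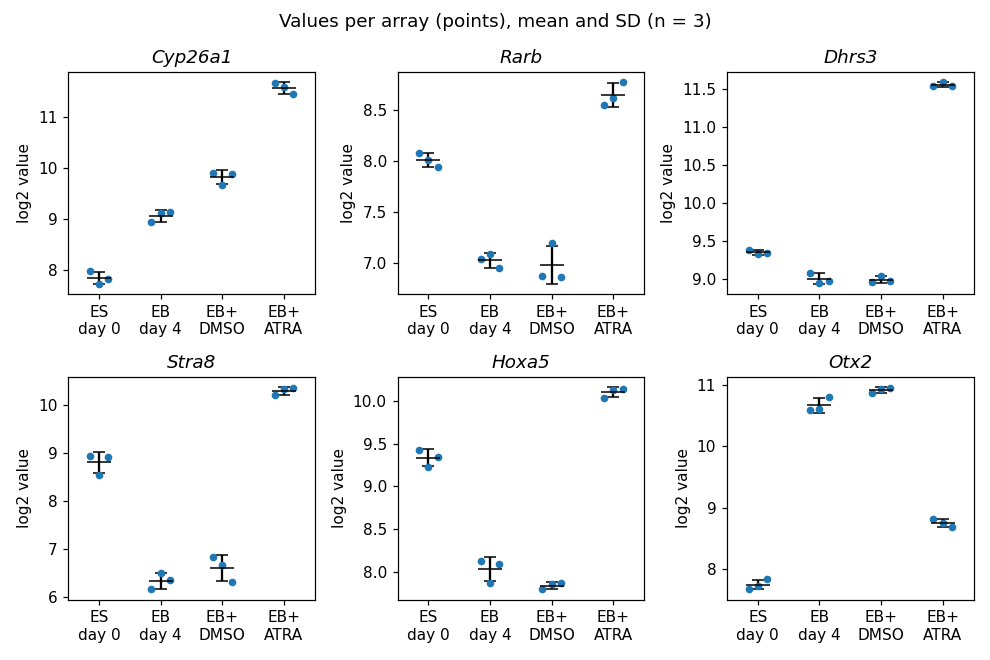
Log2 values of 6 genes in each array (points), with the mean and SD of each group of 3 (bars). Cyp26a1, Rarb, Dhrs3, Stra8 and Hoxa5 are highest with ATRA, and Otx2 is higher in day 4 EBs (10.67 ± 0.12) than in ES cells (7.75 ± 0.08) and lower with ATRA (8.75 ± 0.06) than with DMSO (10.92 ± 0.05).

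ATRA against DMSO set the response to ATRA apart from that to the solvent and to any added time. The largest rise was in Stra8, a gene of meiotic entry, by 3.68 ± 0.14 (12.9-fold). Aqp3, a water and glycerol channel gene, rose by 2.74 ± 0.06 (6.7-fold), and Dhrs3, which encodes a retinaldehyde reductase, by 2.58 ± 0.05 (5.96-fold). Stra6, the gene of the receptor for retinol-binding protein, rose by 1.95 ± 0.06, Cdk15 by 1.72 ± 0.07, and the homeobox genes Hoxa5 and Hoxb5 by 2.27 ± 0.07 and 1.71 ± 0.11. The largest falls were in the long non-coding RNA Platr8 (-2.18 ± 0.07) and in Otx2, a transcription factor gene of the epiblast and anterior brain (-2.17 ± 0.06, or 4.49-fold lower). Foxd3 (-1.59 ± 0.07), Cdh9 (-1.45 ± 0.13), Slc27a2 (-1.24 ± 0.09), the RNA sensor gene Ddx58 (-1.22 ± 0.06), the Wnt pathway transcription factor gene Lef1 (-1.21 ± 0.05) and the calcium-binding protein gene Casq2 (-1.17 ± 0.12) also fell. Each of these 16 genes, Cyp26a1 included, had non-overlapping values in the 3 and 3 arrays, and the adjusted p of Cdh9 was 1.39e-05. Over all genes, 2655 of 19938 passed an adjusted p of 0.05 in limma, 1249 higher and 1406 lower; 342 of them changed at least 1.5-fold and 86 at least 2-fold. The balance of directions depended on the scaling, the variance prior and the genes included: 47% of the called genes were higher, against 54.2% after quantile normalization, 48.3% after median centring, 43% with an intensity trend and 38.5% among genes above the median of mean value. The 3 and 3 values did not overlap for 39.6% of genes, where chance gives 10%. Some calls ended when a single replicate was left out. Hoxc13 lost its call without DMSO 1, DMSO 2, ATRA 2 or ATRA 3 (log2 change -0.25 to -0.23). Meis1 lost its call without DMSO 1, DMSO 3, ATRA 1 or ATRA 3 (log2 change 0.19 to 0.21). Mdm2 lost its call without DMSO 1, DMSO 2, DMSO 3, ATRA 1, ATRA 2 or ATRA 3 (log2 change 0.14 to 0.16). Its limma call also ended with median centring (adjusted p = 0.126), all probe sets (0.0545) and the replicate number as a block (0.0564). Fdps lost its call without DMSO 1, DMSO 2, ATRA 1, ATRA 2 or ATRA 3 (log2 change 0.18 to 0.20). Mvd lost its call without DMSO 1, DMSO 2, ATRA 1, ATRA 2 or ATRA 3 (log2 change 0.19 to 0.26).

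Among retinoid response and metabolism genes, of 21 measured genes, 9 were higher and 1 lower (9 higher and 2 lower adjusted over the list alone). The highest-ranked were Dhrs3, Stra6, Cyp26a1 (1.76 ± 0.09) and Nrip1 (1.06 ± 0.06), and Rarb rose by 1.68 ± 0.09. The list rose against other genes (camera, adjusted p = 3.82e-08; adjusted p = 0.00388 with an estimated correlation). Hox genes of paralogue groups 1 to 5, which pattern the hindbrain and neck, rose together: of 14 measured genes, 9 were higher and 0 lower (11 higher and 0 lower adjusted over the list alone), with Hoxb4 at 1.27 ± 0.05, Hoxa3 at 1.22 ± 0.05 and Hoxb1 at 1.27 ± 0.06 beside Hoxa5. That list had an adjusted p of 1.66e-15, and an adjusted p = 0.00214 with an estimated correlation. These were the only 2 of the 25 lists whose call in this comparison held with an estimated correlation. Of the posterior Hox groups 6 to 13, 5 of 23 rose and 1 fell. Hoxb13 (0.74 ± 0.07), Hoxa7 (0.49 ± 0.06) and Hoxa6 (0.39 ± 0.05) rose, and Hoxc13 fell (-0.25 ± 0.06). The adjusted p of this list was 0.0159, and adjusted p = 0.406 with an estimated correlation. Among hindbrain genes and Hox cofactors, Pbx2 (0.45 ± 0.05) and Meis1 (0.22 ± 0.05) rose and Gbx2 (-0.76 ± 0.05) fell, of 10 measured.

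More pluripotency genes were called lower than higher: of 25 measured genes, 2 were higher and 11 lower, and 12 did not pass (2 higher and 12 lower adjusted over the list alone). Nr5a2 (-0.65 ± 0.05), Zfp42 (-0.57 ± 0.06), Fgf4 (-0.49 ± 0.04) and Tcl1 (-0.42 ± 0.04) fell, while Pou5f1 (0.00 ± 0.04) and Nanog (-0.01 ± 0.05) did not pass the test. The list's adjusted p was 2.05e-04, and adjusted p = 0.222 with an estimated correlation. Feedback genes of FGF and ERK signalling fell in 8 of 11 cases and rose in 2. Spry2 fell by 0.77 on the log2 scale, and Dusp4 (-0.47 ± 0.06), Spry4 (-0.34 ± 0.04) and Il17rd (-0.36 ± 0.05) fell too (list adjusted p = 3.27e-05; adjusted p = 0.116 with an estimated correlation). Of the primed epiblast genes, 2 of 9 rose and 4 fell, with Otx2, Dnmt3b (-0.54 ± 0.05) and Fgf5 (-0.62 ± 0.13) lower and Dnmt3a (0.25 ± 0.05) higher. Against day 4 EBs, ATRA-treated EBs had 3 of these genes higher and 2 lower, with a list median of -4e-05. The immediate early genes Btg2 (-0.56 ± 0.05), Egr1 (-0.52 ± 0.06) and Ier3 (-0.50 ± 0.06) fell, 3 of 12 in all, with an adjusted p of 0.0125 for the list and adjusted p = 0.247 with an estimated correlation. Ier3 was also called higher with DMSO than in day 4 EBs. Against day 4 EBs, 2 of the immediate early genes were higher with ATRA and 3 lower.

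Germ-layer and signalling lists split. The primitive streak list had 4 of 23 genes higher, with Cdx1 at 1.31 ± 0.09 and Wnt3a at 0.46 ± 0.07, and 3 lower, with Cer1 at -0.90 ± 0.09 and Lhx1 at -0.69 ± 0.09. Cer1 and Lhx1 were also called higher with DMSO than in day 4 EBs, so their falls are relative to that raised level. In the mesoderm and cardiac list, Pdgfrb rose by 1.497 ± 0.043 and Gata6 by 0.42 ± 0.05, while Tbx20 (-0.39 ± 0.06) and Bmp4 (-0.30 ± 0.05) fell (6 higher and 3 lower of 26). Endoderm genes were lower in 6 and higher in 2 of 25 cases, among them Dab2 (-0.35 ± 0.06) and Hnf4a (-0.42 ± 0.07) lower and Foxa1 (0.44 ± 0.09) higher. A further Dab2 probe set outside the test did not pass. Against day 4 EBs, ATRA-treated EBs had 7 of these genes higher and 1 lower, so the lower values are relative to the DMSO group. For ATRA against DMSO the endoderm list's adjusted p was 0.00286, and adjusted p = 0.52 with an estimated correlation. Neural progenitor genes split evenly, Msi1 (0.53 ± 0.05) and Pax6 (0.70 ± 0.09) higher and Sox21 (-0.47 ± 0.06) and Ncam1 (-0.39 ± 0.05) lower, and of the neuronal genes Elavl3 rose (0.55 ± 0.04) and Sox11 fell (-0.65 ± 0.12). Germ line genes beside Stra8 included Tfap2c (0.83 ± 0.09), Kit (0.58 ± 0.06) and Dazl (0.38 ± 0.06), all higher, 4 of 12 with 1 lower (list adjusted p = 0.0126; adjusted p = 0.247 with an estimated correlation). Among Nodal and TGF-beta targets, the Nodal antagonist gene Lefty1 rose by 1.29 ± 0.08, and among BMP targets Id4 fell (-0.73 ± 0.05). Genes called higher and lower numbered 2 and 2 of 20 (neural progenitor), 2 and 3 of 19 (neuronal), 3 and 3 of 10 (Nodal and TGF-beta targets) and 2 and 3 of 10 (BMP targets).

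Of the stress and metabolic lists, unfolded protein and integrated stress genes rose in 5 of 11 cases with none lower, such as Ddit3 (0.48 ± 0.05) and Hspa5 (0.25 ± 0.04) (adjusted p = 0.00449; adjusted p = 0.222 with an estimated correlation). Hypoxia and glycolysis genes fell in 5 and rose in 1 of 17, with Ndrg1 at -0.60 ± 0.08 (adjusted p = 0.0442; adjusted p = 0.69 with an estimated correlation). Only Ccnd2 (0.43 ± 0.05) of 22 cell cycle genes passed. The cholesterol synthesis genes Fdps (0.20 ± 0.05) and Mvd (0.25 ± 0.07) and the p53 targets Fas (0.31 ± 0.07) and Mdm2 (0.15 ± 0.04) were higher. Of the Wnt targets, 1 of 12 rose and 3 fell, Axin2 (-0.35 ± 0.07) and Lef1 among the latter. Markers of other cell types moved little as lists. In the fibroblast list Dcn (-0.41 ± 0.06), S100a4 (-0.40 ± 0.07) and Thy1 (-0.36 ± 0.06) fell and Loxl1 (0.23 ± 0.04) rose, of 13 measured. In the blood and endothelium list Pecam1 rose (0.73 ± 0.05) and Cdh5 fell (-0.30 ± 0.05). In the trophoblast list Tfap2c rose and Ascl2 fell (-0.94 ± 0.08). Genes called higher and lower numbered 3 and 2 of 20 (blood and endothelium), 1 and 3 of 12 (trophoblast), 2 and 0 of 9 (p53 targets) and 2 and 0 of 13 (cholesterol synthesis). Median, mean and test differed in sign for the lists Nodal and TGF-beta targets (median below 0, mean above 0, camera down), cell cycle (median below 0, mean above 0, camera down), p53 targets (median below 0, mean above 0, camera up) and fibroblast (median above 0, mean below 0, camera down). No list in this paragraph was called with an estimated correlation. With array weights the number of genes changed was 4311 in place of 2655.

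**Figure D2:**
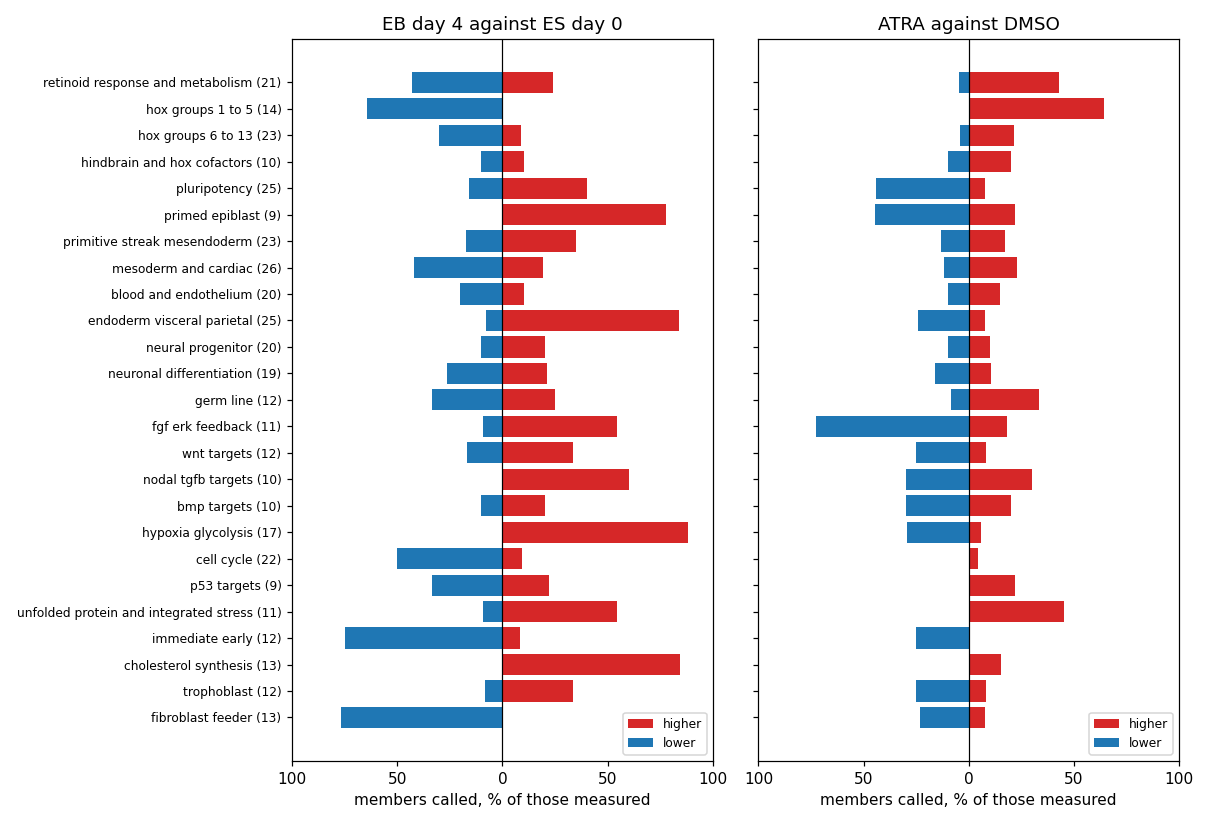
Share of the measured members of each of the 25 gene lists that were called higher (red, to the right) or lower (blue, to the left) in each comparison, in percent, with the number measured in parentheses. Hox groups 1 to 5 had 9 of 14 genes lower in day 4 EBs than in ES cells and 9 higher with ATRA than with DMSO.

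Day 4 EBs against ES cells measured the step to EBs without DMSO or ATRA. Differentiation, aggregation and culture without LIF change together in it and cannot be separated. The largest rises were in Lrp2, the gene of an endocytic receptor of absorptive epithelia (3.39 ± 0.08, 10.5-fold), Lgals2 (3.33 ± 0.09), Ttr, the transthyretin gene of visceral endoderm (3.19 ± 0.12), Gkn2 (3.19 ± 0.11), the pepsinogen gene Pga5 (3.17 ± 0.06), the cathepsin gene Ctsh (2.99 ± 0.08), Otx2 (2.92 ± 0.06) and Pla2g7 (2.84 ± 0.05). Among the genes that the naming rule allows, the largest fall was in Efemp1, an extracellular matrix gene (-3.47 ± 0.07, 11.1-fold lower). Next came Tdpoz3 (-3.39 ± 0.13), Usp17la (-3.36 ± 0.13), Tmem92 (-3.35 ± 0.12), Eif4a3l1 (-3.31 ± 0.23), the chemokine gene Ccl3 (-3.30 ± 0.07), Trim30a (-3.26 ± 0.08) and Medag (-3.24 ± 0.14). Gm5662, a predicted gene that the rule leaves out, fell further (-3.99 ± 0.12). Tdpoz3, Usp17la and Eif4a3l1 have near-identical copies that a probe set may not tell apart. In all, 6925 genes passed, 3558 higher and 3367 lower, and 1433 changed at least 1.5-fold. 

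Endoderm genes rose in 21 of 25 cases and fell in 2 (21 higher and 2 lower adjusted over the list alone), with Cubn (2.35 ± 0.07), Dab2 (1.36 ± 0.06) and Hnf4a (1.11 ± 0.07) beside Ttr, while the other Dab2 probe set, at 0.09, did not pass (adjusted p = 0.514) (list adjusted p = 2.01e-10; adjusted p = 0.091 with an estimated correlation). Primed epiblast genes rose in 7 of 9 cases, such as Zic2 (1.12 ± 0.09) and Fgf5 (1.12 ± 0.13) (list adjusted p = 3.80e-04; adjusted p = 0.0874 with an estimated correlation). Hypoxia and glycolysis genes rose in 15 of 17 cases, with Egln3 (1.96 ± 0.05), Ndrg1 (1.90 ± 0.08) and Bnip3 (1.43 ± 0.07) ahead (list adjusted p = 1.30e-09; adjusted p = 0.091 with an estimated correlation). Cholesterol synthesis genes rose in 11 of 13 cases, by smaller amounts such as 0.60 ± 0.06 for Lss (list adjusted p = 9.14e-06; adjusted p = 0.0874 with an estimated correlation). Stress genes such as Chac1 (1.14 ± 0.06) and Herpud1 (0.80 ± 0.05) rose in 6 of 11 cases and fell in 1 (list adjusted p = 0.00184; adjusted p = 0.0961 with an estimated correlation). Nodal and TGF-beta targets rose in 6 of 10, among them Foxh1 (0.83 ± 0.05) (list adjusted p = 0.00994; adjusted p = 0.091 with an estimated correlation), and FGF feedback genes in 6 of 11, among them Il17rd (0.57 ± 0.05), with 1 lower (list adjusted p = 0.0447; adjusted p = 0.326 with an estimated correlation).

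Fibroblast markers fell in 10 of 13 cases (0 higher and 12 lower adjusted over the list alone): S100a4 stood at -2.30 ± 0.07, Thy1 at -1.82 ± 0.06, Dcn at -1.78 ± 0.06 and Loxl1 at -1.32 ± 0.04 (list adjusted p = 2.65e-09; adjusted p = 0.0538 with an estimated correlation). With them fell immediate early genes, 9 of 12 with 1 higher, led by Egr1 (-1.98 ± 0.06), Fos (-1.80 ± 0.08) and Jun (-1.21 ± 0.06) (list adjusted p = 3.80e-04; adjusted p = 0.091 with an estimated correlation). Hox groups 1 to 5 fell in 9 of 14 cases with none higher, Hoxa5 at -1.31 ± 0.07 and Hoxa2 at -1.12 ± 0.08 (list adjusted p = 8.44e-05; adjusted p = 0.0705 with an estimated correlation). Of the mesoderm and cardiac genes 11 fell, with Prrx1 at -1.84 ± 0.07 and Pdgfrb at -1.05 ± 0.04, and 5 rose, with Tbx20 at 1.22 ± 0.06 (list adjusted p = 0.044; adjusted p = 0.442 with an estimated correlation). Cell cycle genes fell in 11 of 22 cases and rose in 2, with Ccnd1 at -1.36 ± 0.05 (list adjusted p = 0.00994, and adjusted p = 0.326 with an estimated correlation). Without ES replicate 2 and EB replicate 2 they fell in 6 cases and rose in 1 (camera, list adjusted p = 0.0316, and adjusted p = 0.314 with an estimated correlation). None of the lists of this comparison kept its call with an estimated correlation.

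The other lists were not called as sets. Retinoid genes went both ways, with Cyp26a1 (1.22 ± 0.09) and Rdh11 (0.58 ± 0.06) higher and Crabp1 (-1.47 ± 0.05) and Rarb (-0.99 ± 0.09) lower. Pluripotency genes were higher in 10 and lower in 4 of 25 cases, Fgf4 (0.73 ± 0.04) and Nr0b1 (0.72 ± 0.05) up and Fbxo15 (-0.90 ± 0.07) down. Posterior Hox genes fell in 7 and rose in 2 of 23, such as Hoxa6 (-0.63 ± 0.05). Of the germ line list Prdm1 rose by 2.26 ± 0.07 and Stra8 fell (-2.47 ± 0.14). Eomes (0.90 ± 0.07) and Lhx1 (0.90 ± 0.09) of the primitive streak list, Lef1 (1.18 ± 0.05), Notum (1.42 ± 0.08) and Dkk1 (1.33 ± 0.10) of the Wnt targets rose. Flt1 (1.23 ± 0.07) of the blood and endothelium list, Sox21 (1.04 ± 0.06) of the neural progenitor list, Sox11 (1.01 ± 0.12) of the neuronal list, Meis2 (1.06 ± 0.06) of the hindbrain list, Id4 (0.59 ± 0.05) of the BMP targets and Krt19 (1.11 ± 0.07) of the trophoblast list rose. Gata2 (-0.92 ± 0.05), Stmn2 (-0.97 ± 0.08) and the p53 target Fas (-0.96 ± 0.07) fell. Genes called higher and lower numbered 5 and 9 of 21 (retinoid), 3 and 4 of 12 (germ line), 8 and 4 of 23 (primitive streak), 4 and 2 of 12 (Wnt targets), 2 and 4 of 20 (blood and endothelium), 4 and 2 of 20 (neural progenitor), 4 and 5 of 19 (neuronal), 1 and 1 of 10 (hindbrain and Hox cofactors), 2 and 1 of 10 (BMP targets), 4 and 1 of 12 (trophoblast) and 2 and 3 of 9 (p53 targets). Median, mean and test differed in sign for the lists hindbrain and Hox cofactors (median below 0, mean above 0, camera down), neuronal (median above 0, mean below 0, camera down), BMP targets (median below 0, mean above 0, camera up) and p53 targets (median above 0, mean below 0, camera down).

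DMSO-treated against day 4 EBs held the solvent together with any added time, which the labels leave open, and these cannot be separated. The genes that rose most included the visceral endoderm genes Apoa1 (1.04 ± 0.10, adjusted p = 0.00662), Ttr (0.97 ± 0.12, adjusted p = 0.0119) and Apob (0.77 ± 0.11, adjusted p = 0.0119), with Clic6 (0.76 ± 0.11), Cyp26a1 (0.75 ± 0.09), Tmprss2 (0.75 ± 0.11), Slc7a8 (0.71 ± 0.09) and Amot (0.68 ± 0.09). Those that fell most included the non-coding RNA Malat1 (-0.79 ± 0.13), Klk1b11 (-0.66 ± 0.13) and Fmc1 (-0.43 ± 0.06). Malat1 and Klk1b11 lost their calls with the replicate number as a block (limma, adjusted p = 0.0536 for each). In the endoderm list 5 of 25 genes rose, and 12 when adjusted over the list alone (list adjusted p = 9.45e-12; adjusted p = 0.187 with an estimated correlation). Cer1 (0.66 ± 0.09) and Lhx1 (0.64 ± 0.09), Krt18 (0.44 ± 0.07) and Krt8 (0.24 ± 0.05), and Ier3 (0.36 ± 0.06) and Zfp36 (0.42 ± 0.08) rose in their lists. The primed epiblast list was called with no gene passing over all genes (adjusted p = 0.00236; adjusted p = 0.187 with an estimated correlation), Fgf5 standing at 0.52 ± 0.13. The retinoid, hypoxia and trophoblast lists had adjusted p of 0.0278, 0.0264 and 0.0264, and adjusted p of 0.187, 0.725 and 0.494 with an estimated correlation. In total 149 genes passed, 107 higher and 42 lower, and 18 changed at least 1.5-fold. Median, mean and test differed in sign for the lists hox groups 6 to 13 (median below 0, mean below 0, camera up), hindbrain and Hox cofactors (median below 0, mean below 0, camera up), pluripotency (median below 0, mean below 0, camera up), fgf erk feedback (median below 0, mean above 0, camera up), Wnt targets (median below 0, mean above 0, camera up), Nodal and TGF-beta targets (median below 0, mean above 0, camera up), BMP targets (median below 0, mean above 0, camera up) and cell cycle (median below 0, mean below 0, camera up).

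The number of calls depended on single arrays. Without DMSO replicate 1, or without EB replicate 1, limma called 0 genes (2340 and 3080 at an unadjusted p under 0.05). Without DMSO replicate 3 it called 2, without EB replicate 2 it called 33 and without EB replicate 3 it called 48. The changes of Apoa1 and Cyp26a1 stayed close to their sizes with all arrays while their calls ended. Without EB replicate 1 and without DMSO replicate 1, Apoa1 stood at 1.001 (adjusted p = 0.0548) and 1.003 (adjusted p = 0.0668), and Cyp26a1 at 0.688 (adjusted p = 0.0602) and 0.707 (adjusted p = 0.0788). The share of called genes that were higher was 71.8%, against 57.7% after quantile normalization and 87% after median centring. Of the 107 genes that rose, 64 had also risen from ES cells to day 4 EBs, where independent lists would share 19.1, and 21 had fallen (18.1). Of the 42 genes that fell, 21 had risen (7.495 for independent lists) and 6 had fallen (7.09). Both comparisons use the EB arrays, which pushes them apart: their covariance across genes was 0.00295, and -0.00303 in simulated arrays without any change. Of the same 107 genes, 40 fell with ATRA against DMSO (7.55 for independent lists), but those comparisons share the DMSO arrays, and their covariance of -0.00503 compares with -0.00302 in the simulation. Part of that excess may come from the shared arrays, which are too few to split.

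ATRA-treated against day 4 EBs, which adds the solvent and any added time to the ATRA response and shares the ATRA arrays with the first comparison, changed 3673 genes, 1553 higher and 2120 lower. The share higher was 42.3%, and 50.3% after median centring. Stra8 (3.96 ± 0.14), Aqp3 (2.64 ± 0.06), Dhrs3 (2.57 ± 0.05), Cyp26a1 (2.51 ± 0.09), Hoxa5 (2.08 ± 0.07), Stra6 (1.98 ± 0.06), Dusp9 (1.70 ± 0.07) and Greb1l (1.70 ± 0.07) rose most. Platr8 (-2.27 ± 0.07), Otx2 (-1.92 ± 0.06), Cdh9 (-1.59 ± 0.13), Foxd3 (-1.59 ± 0.07), Ddx58 (-1.25 ± 0.06), Enox1 (-1.22 ± 0.08), Casq2 (-1.19 ± 0.12) and the melanocortin receptor gene Mc5r (-1.17 ± 0.10) fell most. The retinoid list (10 of 21 higher) and Hox groups 1 to 5 (9 of 14 higher) were called, each with an adjusted p = 0.00143 with an estimated correlation. The other lists called, Hox groups 6 to 13, pluripotency, germ line and FGF feedback, did not hold with it. Median, mean and test differed in sign for the lists primed epiblast (median below 0, mean below 0, camera up), blood and endothelium (median below 0, mean above 0, camera up) and neuronal (median above 0, mean below 0, camera up). 

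For many genes, the ATRA response ran against the change from ES cells to day 4 EBs. That change is not differentiation alone, and the opposition is not read as a return to the ES state. Of 25 pluripotency genes, 10 were higher and 4 lower in EBs, and 2 were higher and 11 lower with ATRA. Of the 1249 genes that rose with ATRA against DMSO, 579 had been lower in day 4 EBs than in ES cells, against 211 for independent lists, and 155 had been higher, against 223. Of the 1406 that fell with ATRA, 778 had been higher in day 4 EBs (251 for independent lists) and 256 lower (237). Otx2, Lef1 and Pdgfrb are examples: Otx2 changed by 2.92 ± 0.06 from ES cells to EBs and by -2.17 ± 0.06 with ATRA, Lef1 by 1.18 ± 0.05 and -1.21 ± 0.05, and Pdgfrb by -1.05 ± 0.04 and 1.497 ± 0.043. Among genes that changed at least 1.5-fold with ATRA, 146 of 207 that rose had been lower in EBs and 108 of 135 that fell had been higher. Cyp26a1 rose in both comparisons. The falls with ATRA are measured from the DMSO group, where 40 of the 1406 genes had been called higher than in day 4 EBs. In all, 1357 genes changed in opposite directions and 411 in the same direction, the latter 271 without ATRA replicate 3. These comparisons share no array. Across all 19938 genes, which are not independent replicates, the changes had a Pearson correlation of -0.26 and a Spearman correlation of -0.24.

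**Figure D3:**
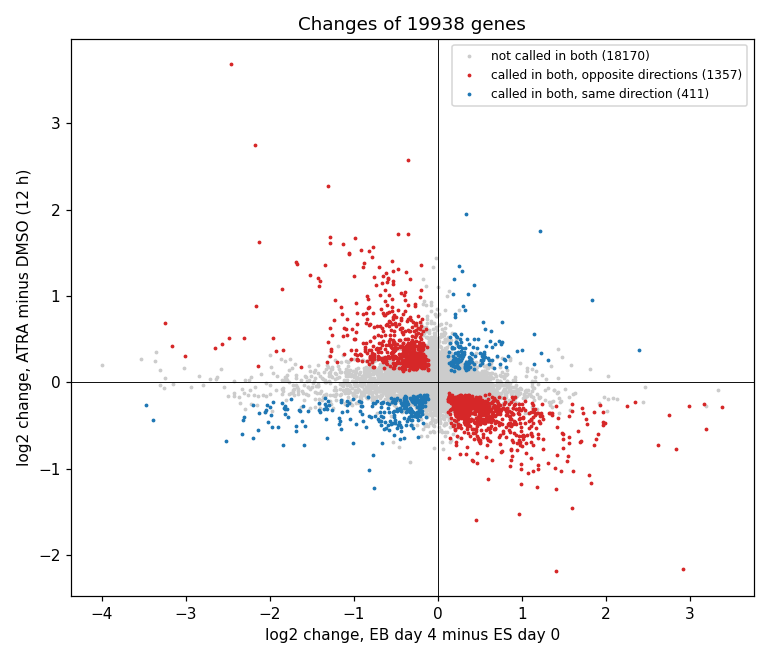
Log2 change of each gene from ES cells to day 4 EBs (horizontal) against its log2 change with ATRA against DMSO (vertical). Genes called in both comparisons are red where the directions are opposite (1357 genes) and blue where they are the same (411 genes).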

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

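All tests of explanations in this part, the counts over splits included, were written down after the results were seen.

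A signal appeared in data that the gene comparisons do not use: of the 13767 probe sets with no or several gene symbols, 459 differed between ATRA and DMSO (limma over all probe sets, adjusted p under 0.05). Of these, 182 were higher with ATRA, by up to 1.87 on the log2 scale, and 277 were lower, down to -1.501. Among the genes of the main fit, 2655 of 19938 (13.3%) were called, a larger share. In DMSO against day 4 EBs, 300 of these 13767 probe sets were called, 259 higher and 41 lower, so calls among them are not particular to ATRA. They carry no single gene name and were not followed further.

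Each comparison has 10 splits of its 6 arrays into 3 and 3, too few for a share under 0.05. For ATRA against DMSO the real split called 2655 genes and the highest other 0; for day 4 EBs against ES cells 6925 and 273; for DMSO against day 4 EBs 149 and 0; and for ATRA against day 4 EBs 3673 and 0. In each case 1 of the 10 splits, the real one, gave as many. The other splits mix the groups and so hold less of the difference between them. Their counts shrink for that reason, whatever the cause, and no conclusion is drawn from them.

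The opposition of the ATRA response to the change from ES cells to day 4 EBs was weighed as a pattern. The fibroblast list did not return with ATRA: its median change was 0.00184 (95% bootstrap interval -0.112 to 0.131, over genes and not arrays). Regain in step with the raised genes of the pattern would need 0.931, so fibroblasts both lost and regained do not account for those genes. The test does not cover a loss of fibroblasts alone, which could have made the earlier fall of genes that ATRA then raised in other cells. Mean intensity and the main axis of variation within groups carried 4.82% of the covariance of the comparisons (interval 4.16 to 5.41). That axis held 37.4% of the within-group variance. It ran mostly through ES and EB arrays (loading 0.61 for ES replicate 1 and -0.533 for ES replicate 2). The DMSO and ATRA arrays loaded between -0.0803 and 0.0672. A technical difference between whole groups lies outside such an axis, so this share cannot decide whether the normalization or array quality was the main source. Without ES replicate 2 and EB replicate 2, 1378 genes were opposed. Of the 10 splits of the ATRA and DMSO arrays, 1 gave as many opposed genes (1357 in the real split, 0 in the highest other), too few to judge chance; a first test on the correlation gave 0.264 in the real split and 0.241 in the highest other, and was replaced after that was seen because a correlation does not shrink when a split mixes the groups. The covariance was 0.0188 in the real split and at most 0.0082 in the others. A split that mixes the groups holds less of the difference between them. Its covariance and its count of opposed genes shrink for that reason, whatever the cause, so no conclusion is drawn from either. A first test of the normalization, the correlation after the technical terms were taken out, had stayed at -0.264 and was replaced too. A biological candidate explanation is lower retinoid signalling in day 4 EBs than in ES cells, but of the 9 retinoid-list genes that rose with ATRA, 5 had been lower in EBs and 3 higher, which leaves it open.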

How the results depend on the processing

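The alternative without ES replicate 2 and EB replicate 2 was chosen after seeing the data; the others were planned. With each array of the groups compared left out in turn, the genes changed numbered 1868 to 2066 for ATRA against DMSO, 6013 to 7102 for day 4 EBs against ES cells, 0 to 128 for DMSO against day 4 EBs and 2495 to 3411 for ATRA against day 4 EBs, and 1003 to 1536 genes were opposed. Without ES replicate 2 and EB replicate 2, which are outside the groups of ATRA against DMSO but inside its fit, that comparison gave 3122. Array weights, which gave ES replicate 3 a weight of 7.25 and ES replicate 1 one of 0.289, raised ATRA against DMSO to 4311 and the opposed genes to 2166. An adjusted p of 0.01 left 1605, 5 (DMSO against day 4 EBs), 2126 (ATRA against day 4 EBs) and 814 opposed genes. The 1.5-fold limit left 342, 1433, 18, 372 and 157, in the order above; both limits are stricter by construction. DMSO against day 4 EBs also gave 253 genes after quantile normalization, 365 and 761 with the filters on mean value, 476 with all probe sets, 626 with an intensity trend, 25 with only its 2 groups and 27 without ES replicate 2 and EB replicate 2; the cause was not tested. Over the genes that the naming rule covers and these settings, calls were lost in 48 cases for ATRA against DMSO, 4 for day 4 EBs against ES cells, 141 for DMSO against day 4 EBs and 62 for ATRA against day 4 EBs, and no call changed sign.

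Replicate numbers did not pair the samples across all groups: of 18 same-number pairs, 2 had correlated deviations above 0.1 (range -0.126 to 0.506). Both joined ES and EB arrays, replicate 2 at 0.506 and replicate 1 at 0.303, while replicate 3 stood at -0.065. ES replicate 1 correlated about as well with EB replicate 3 (0.312). A batch shared by some ES and EB arrays is therefore possible and was not tested. Of 12 arrays, 3 correlated best with their own number. With the replicate number as a block, the counts were 2553, 6848, 62 and 3514 genes and 1284 opposed genes, and 1 list call (FGF feedback, day 4 EBs against ES cells) passed the threshold no longer, with an adjusted p = 0.0553. With fry in place of camera, 0 list calls were lost for ATRA against DMSO, day 4 EBs against ES cells and ATRA against day 4 EBs. In the same order, 7, 9 and 8 lists were newly called. For DMSO against day 4 EBs, 2 list calls were lost and 2 were added. Unlike camera, fry does not set a list against the other genes, so it answers a different question from the estimated correlation. The deposited table gives no background signal, so what signal over background limits was not analysed here.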

Other observations

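The lists and tests of explanations in this part were chosen after the values were seen. Interferon-stimulated genes were lower in day 4 EBs than in ES cells in 28 of 30 cases, with Usp18 (-3.24 ± 0.11), Oasl2 (-2.65 ± 0.10), Mx2 (-2.54 ± 0.16) and Ifit3 (-2.42 ± 0.14) as examples. Fibroblast markers fell in the same comparison (10 of 13), and which cells the interferon-stimulated transcripts came from was not tested. With ATRA against DMSO, 3 interferon-stimulated genes were higher and 5 lower, among the latter Ddx58 (-1.22 ± 0.06), Irgm1 (-0.73 ± 0.09) and Xaf1 (-0.71 ± 0.06). Genes known from the 2-cell-stage embryo fell from ES cells to EBs in 14 of 15 cases. Zfp352 (-2.93 ± 0.08) and Arg2 (-3.01 ± 0.08) are examples. Several belong to families of near-identical copies, so single members are uncertain. Since these lists were drawn up from genes seen to fall, their counts are descriptions.

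In the imprinted region from Dlk1 to Dio3, whose gene order was taken from GRCm38.p6, some genes were lower with ATRA. Of 48 measured, 17 were lower and 0 higher; of the 45 that are not protein-coding, 16 were lower. Over all 48, the median change was -0.246 (95% bootstrap interval -0.339 to -0.141). That interval reflects the spread between genes, taken as independent, and not the spread between arrays. Mir377 (-1.52 ± 0.15), Mir300 (-1.01 ± 0.11), Meg3 (-0.77 ± 0.14) and Rian (-0.41 ± 0.09) are examples. From ES cells to EBs, 15 of the 48 genes had been called higher and 2 lower. All of these examples had risen, such as Meg3 (0.87 ± 0.14), so their falls are also part of the opposition described above. Against a shift of small-RNA probe sets or of this signal level, the median was 0.0568 in 164 other microRNA genes of like level and 0.0301 over random gene sets of like mean value; with any 1 DMSO or ATRA array left out, the region's weakest median was -0.224. With an estimated correlation the region's adjusted p was 0.199 (camera, over the lists drawn up afterwards), so correlated behaviour of neighbouring genes limits this pattern. An effect of ATRA on the region is a hypothesis found on these data, and probe sets that read a shared precursor were not tested.

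All 6 measured genes of the Mir17 cluster were lower with ATRA, with Mir17hg at -0.50 ± 0.10. They belong to one host transcript, and the list's adjusted p of 9.52e-06 became 0.199 with an estimated correlation of 0.562 (camera).

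The fall of fibroblast markers from ES cells to EBs was the last pattern weighed. It did not come from ES replicate 2 and EB replicate 2, since 11 of 13 genes were lower without them and 10 with all arrays. Fibroblasts carried in the ES cultures are a candidate source, which the labels neither name nor exclude. Of the abundant fibroblast collagens, 2 of 3 were lower, Col1a1 (-0.87 ± 0.07, at 9.82 ± 0.15 in ES cells) and Col1a2 (-1.07 ± 0.07, at 9.54 ± 0.10), while Col3a1 (-0.24 ± 0.09, at 8.42 ± 0.14) did not pass. A change within the ES-derived cells cannot be told apart from such fibroblasts here, because no value in these data separates the sources.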
